A study of Mus musculus with 4 samples.

How the data were processed

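Total RNA of wild-type mouse growth plate-like chondrocytes cultured for 1, 3, 5 or 10 days was extracted with a column kit and made into libraries after depletion of ribosomal RNA, per the labels' protocols. The submitters' processing notes name STAR, featureCounts and edgeR without versions and the mouse build GRCm38. The annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. The deposited table holds a normalized signal per gene symbol for 24499 genes and 15 libraries. The labels give 1 sample per day, and each column was taken as a library of the sample of its day by the day in its name.

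The unit of the deposited signal was worked out from its values. In each column 100% of values were whole multiples of the smallest value above 0, with a tolerance of 0.001, so the smallest value was taken as 1 read. The column totals were 949878 to 1095441 and equalled the total of unscaled CPM divided by edgeR's TMM factor computed from the recovered reads, with a largest difference of 0%. The deposited values are therefore CPM scaled by TMM, and are called CPM here. They were used as deposited. The recovered totals were 12492537 to 18841621 reads per library, and 6538 genes had 0 reads in all libraries. Recovery was tested on simulated data. With all genes simulated, 100% of values were recovered in every library. With only the genes past the filter simulated, 2 libraries failed because their smallest count was 2 reads, so the step needs genes with a single read. In the real libraries 270 to 992 genes held the smallest value. That value was taken as 1 read, so this number cannot test the step, and only the whole multiples bear on it. Of the symbols, 23661 matched GENCODE M21, which is on GRCm38 and gave the coordinates, and 554 matched neither it nor the RefSeq table. Mitochondrially encoded genes were not analysed here, since 0 of the table's symbols belong to them.

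The main value of a gene was the mean over the libraries of a day of log2(CPM + 1), and a log2 difference is the difference of 2 day means on that scale, which understates the change of genes near 0. Genes with a mean of 1 CPM or more over the 4 day means were kept, 12109 in all. The design fixed before the data were examined treated each day as 1 sample and described it by counts of genes at least 2-fold higher or lower. It named, as an alternative for a table with several columns per sample, limma with a trended prior on log2(CPM + 1), all libraries in 1 fit, each library as a replicate, and Benjamini-Hochberg adjustment at 0.05. Both are reported. Every adjusted p in the text comes from that limma fit unless another tool is named, and a gene is said to rise or fall only where it passed. The comparisons against day 1 share its 3 libraries. A gene in a monotone course had a higher, or lower, day mean at each of the 3 steps, whether or not a step passed the test, and a difference of 1 or more (log2) in all.

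There were 37 gene lists fixed before the data were examined, covering chondrocyte stages, matrix, signalling, the cell cycle, stress and metabolism, and other cell types. Members with a mean of 1 CPM or more were used. For each list the number of members that rose or fell was counted over all genes tested and adjusted over the list alone. The list median was also placed among 10000 random lists of the same size matched in 20 bins of mean expression, where lists had at least 4 such members, as a description of these libraries. The genes named were fixed by rule. They were 23 genes of growth plate biology, the 10 highest and 10 lowest log2 differences for day 10 against day 1 and the 5 highest and 5 lowest for the other comparisons (at 5 CPM or more on either day, without predicted, small RNA and clone genes), and up to 3 highest and 3 lowest members per list. C4a and Ube2c are mentioned only as neighbours or copies, and white blood cell markers and Nt5dc1 only in tests of explanations. Intervals on a ratio of reads are exact conditional binomial intervals at 95% from reads pooled by day. Reads without molecular identifiers are not independent molecules, so these intervals cover counting error only.

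In simulated data with the real means, depths and dispersions and 12109 genes, where 200 genes were changed for day 10 against day 1, limma called 63% of the 2-fold and 94% of the 4-fold changes with the right sign, and 4.8% of its calls were unchanged genes. There, 58 unchanged genes reached 2-fold. For day 5 against day 3, where no gene was changed, it called 0. Of 100 simulated lists of 20 unchanged genes, 5 fell outside the 2.5 to 97.5 percentile. The simulated libraries were independent and had the same dispersion per gene on every day. The real libraries spread most on day 10, and same-numbered ones tended to share deviations. These rates therefore do not give limma's error in the real data.

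The alternatives were pseudocounts of 0.25 and 5 CPM, no filter or a filter of 5 CPM, median-ratio and upper-quartile scaling, leaving out small RNA genes, leaving out days for the monotone course, a threshold of 2 (log2), list means, counting intervals and leaving out each library number. Added after seeing the data were edgeR's quasi-likelihood test on the recovered reads, blocks by library number or by libraries 1 and 2 against 3 and 4, fits on parts of the libraries, each library left out, plain CPM and the log2 of the day mean. The work used R 4.3.3, limma 3.58.1, edgeR 4.0.16, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.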

Results

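RNA sequencing followed a wild-type mouse line of growth plate-like chondrocytes through 10 days of culture. The growth plate is the cartilage at the ends of growing bones, where round chondrocytes divide, then become prehypertrophic and hypertrophic before mineralization. Total RNA was taken after 1, 3, 5 or 10 days of culture, and ribosomal RNA was depleted before library preparation. The series title ties the work to human height and to genes active in the layer of round chondrocytes. The labels list 1 sample per day, 4 in all, while the expression table holds 15 libraries. Day 1 has 3 libraries, numbered 1, 3 and 4, and days 3, 5 and 10 have 4 each. The labels do not say what the library numbers stand for, so whether the libraries of a day came from separate cultures is open, and the p-values below measure only the spread between libraries, which may be technical. The libraries held 12492537 to 18841621 reads assigned to genes. At this depth 1 read was worth 0.0523 to 0.0787 CPM, the deposited unit of reads scaled to library size.

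The day 1 libraries stood apart from all later ones. The first principal component of 12109 expressed genes held 49.8% of the variance. On it day 1 stood at one end and days 5 and 10 at the other. Days 5 and 10 overlapped there, with library 2 of day 5 at 30.6 and library 2 of day 10 at 26.9. Pearson's r across genes between the day means was 0.957 for days 1 and 3, 0.917 for days 1 and 5, and 0.904 for days 1 and 10. Neighbouring later days were closer, at 0.978 for days 3 and 5 and 0.9748 for days 5 and 10, and days 3 and 10 stood at 0.954. Genes are not independent replicates, so these values describe the profiles only. Within a day, r between libraries was 0.9902 to 0.9971 on day 1, 0.972 to 0.997 on day 3, 0.967 to 0.995 on day 5 and 0.920 to 0.978 on day 10, so day 10 had the widest spread. Libraries 3 and 4 of days 1, 3 and 5 were the closest pairs of their days, yet their reads differed by more than counting noise, with a chi-square per degree of freedom of 6.19, 5.15 and 14.8. The other pairs of those days stood at 21.9 to 114. Limma's fit counts libraries 3 and 4 as separate replicates. If they came from the same culture, the adjusted p-values below are too small.

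**Figure D1:**
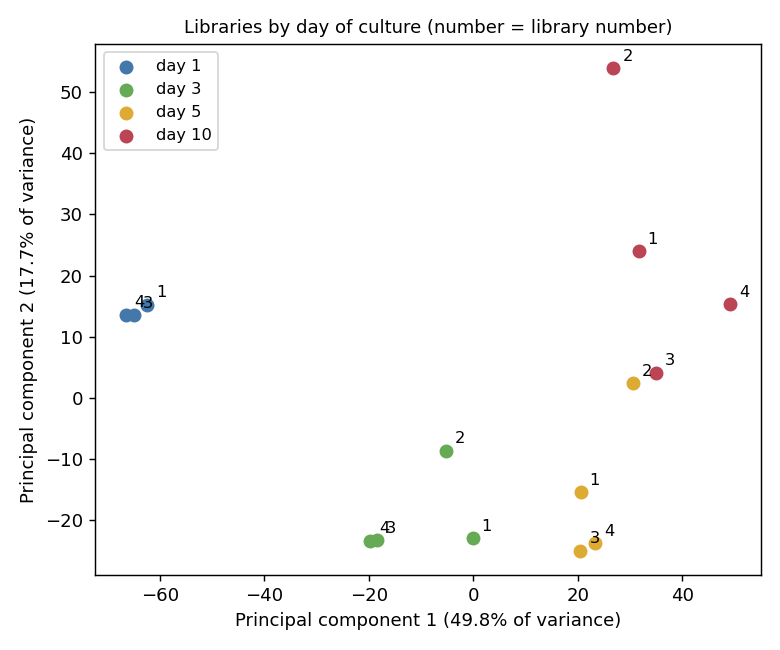
Principal components 1 (49.8% of the variance) and 2 (17.7%) of log2(CPM + 1) over 12109 genes, in arbitrary units. Each point is 1 of the 15 libraries, coloured by day of culture and labelled with its library number. The day 1 libraries lie apart from all later libraries on component 1, and the 4 libraries of day 10 are the most spread.

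The first comparison asked what changed between day 1 and day 3 of culture. Genes of the cartilage matrix rose. Matn1, which encodes the cartilage protein matrilin-1, went from 0.897 CPM on day 1 to 139 on day 3, a log2 difference of 5.94 ± 0.79 (SE, adjusted p = 8.5e-05, n = 3 and 4 libraries). The leucine-rich proteoglycans decorin (Dcn) and lumican (Lum) rose by 5.35 ± 0.33 and 4.79 ± 0.43 on the log2 scale, Matn4 by 4.69 ± 0.35 and Itgbl1 by 4.55 ± 0.35. Of the 18 measured genes of the cartilage matrix list, 12 rose and 0 fell, and 14 rose when adjusted over the list alone. The list median was 1.73 ± 0.57 (SD between libraries) above day 1. Col2a1, which encodes the main collagen of cartilage, rose from 3296 to 11815 CPM (log2 1.74 ± 0.61, adjusted p = 0.039). Of the 11 measured resting and round chondrocyte genes, 6 rose and 1 fell, also when adjusted over the list alone. Clu (29.6 to 183 CPM) and Mgp (2.36 to 45.6 CPM) were among those that rose.

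Col10a1, the collagen of hypertrophic cartilage, had the lowest log2 difference of the named genes on day 3. It fell from 164 ± 55.8 CPM (SD, n = 3) on day 1 to 7.17 ± 0.758 (n = 4) on day 3, a log2 difference of -4.28 ± 0.58 (adjusted p = 9.8e-05). Tnn (tenascin N), Ltbp1 (a protein that binds latent TGF-beta), Ankrd1 and Alpl, the alkaline phosphatase of mineralizing cells, fell too, with log2 differences of -3.74, -3.72, -3.56 and -3.41. Runx2, a transcription factor of hypertrophic chondrocytes and osteoblasts, fell from 205 to 80.01 CPM (adjusted p = 0.002). Their lists went both ways. Of the 18 measured hypertrophic and mineralizing genes 5 rose and 4 fell, with a list median of 0.10 ± 0.05, and of the 14 prehypertrophic genes 2 rose and 2 fell, both also adjusted over the list alone. Pth1r, the receptor of parathyroid hormone-related protein, rose (log2 2.05 ± 0.53, adjusted p = 0.0088). Cell cycle genes fell as well. Of 25 S phase genes 18 fell and 0 rose, and of 25 G2 and M phase genes 20 fell and 0 rose (21 and 23 fell when adjusted over the list alone). Mki67, a marker of dividing cells, was at 699 CPM on day 1 and 373 on day 3, which did not pass the test (adjusted p = 0.087). Genes for cytosolic ribosomal proteins moved the other way, with 28 of 35 higher and 0 lower (33 and 0 adjusted over the list alone) and a list median of 0.59 ± 0.22. In all, 667 genes were at least 2-fold higher on day 3 than on day 1 and 355 at least 2-fold lower. Of these, 637 and 348 also passed limma's test at an adjusted p of 0.05. At any size limma called 1896 genes higher and 1951 lower. Leaving out the libraries numbered 3 lowered the called genes to 830 and 724, leaving out those numbered 1 to 878 and 705, and without library 4 of day 1 the lower ones were 1267.

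The second comparison set day 5 against day 1. The proteoglycan genes were higher still, with Dcn at 571 CPM (log2 6.96 ± 0.33, adjusted p = 7.3e-09) and Lum at 401 CPM (log2 6.27 ± 0.43). Mgp, an inhibitor of matrix calcification, rose from 2.36 to 232 CPM, and Gpnmb, a transmembrane glycoprotein, from 1.11 to 153 CPM. The complement gene C4b had 2 reads on day 1 and 10912 on day 5, a ratio of 3718 with a 95% counting interval of 1029 to 30705, and its near-identical copy C4a makes the value uncertain. Col10a1, Tnn, Tnc, Ltbp1 and Ptgs2 fell most among named genes, with log2 differences of -4.73, -4.03, -3.26, -3.18 and -3.16. Aggrecan (Acan), the large proteoglycan of cartilage, fell from 438 to 149 CPM (log2 -1.78 ± 0.55, adjusted p = 0.015), and the chondrocyte transcription factor genes Sox9 and Sox6 fell by 1.26 and 1.41 on the log2 scale (adjusted p = 0.013 and 0.00025). Sox5 rose by 0.62 on the log2 scale (adjusted p = 0.044), and on day 10 it did not pass the test (adjusted p = 0.198). Of the 18 cartilage matrix genes 9 rose and 2 fell, with a list median of 0.99 ± 0.52, and of the 12 chondrogenic regulators 3 rose and 4 fell, both also adjusted over the list alone. Of the 11 resting and round chondrocyte genes 6 rose and 2 fell (8 and 2 adjusted over the list alone). All 25 S phase genes and all 25 G2 and M phase genes fell, over all genes and adjusted over the list alone, with list medians of -1.01 ± 0.03 and -2.02 ± 0.42. Mki67 stood at 214 CPM (adjusted p = 0.0016). Of the 27 lysosome and autophagy genes 25 rose and 0 fell, of the 35 ribosomal protein genes 31 rose and 0 fell, and of the 27 genes of the secretory pathway and unfolded protein response 0 rose and 18 fell. Adjusted over the list alone these were 25 and 0, 33 and 0, and 0 and 19. Altogether 1268 genes were at least 2-fold higher and 774 at least 2-fold lower, of which 1232 and 766 passed limma's test. At any size limma called 3052 higher and 2998 lower, which became 1979 and 1846 without the libraries numbered 3.

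The third comparison spanned the whole course, day 10 against day 1. Many genes of the prehypertrophic and mineralizing stages rose, and some fell. Pth1r lies on chromosome 9 at 110722085 to 110747145 (GRCm38). It rose from 1.69 ± 0.343 CPM on day 1 through 11.7 on day 3 and 39.5 on day 5 to 217 ± 179.8 on day 10, a log2 difference of 6.01 ± 0.53 (adjusted p = 7.6e-07). Ibsp, which encodes bone sialoprotein, lies on chromosome 5 at 104299171 to 104311469. It had 1 read on day 1 and 37840 on day 10, a ratio of 26809 with a 95% counting interval of 4811 to 1058900.0. On day 10 the libraries numbered 1 to 4 held 324, 1824, 35.5 and 19.7 CPM. The hedgehog target Gli1 rose from 3.9 to 41.3 CPM and Sp7, an osteoblast transcription factor, from 2.82 to 78.7 CPM (log2 3.46 ± 0.84, adjusted p = 0.0032). Ihh, the signal made by prehypertrophic chondrocytes, had 2 reads on day 1 and 378 on day 10, a ratio of 134 with a 95% counting interval of 36.8 to 1109.7. Mmp13, a collagenase, had 2 and 1114 reads, a ratio of 395 (109 to 3262.5). Of the 14 measured prehypertrophic genes 10 rose and 0 fell, also adjusted over the list alone. Of the 18 hypertrophic and mineralizing genes 9 rose and 3 fell, or 11 and 4 adjusted over the list alone. The fallen ones included Col10a1, on chromosome 10 at 34389981 to 34397085, at 31.6 CPM on day 10 (log2 -2.82 ± 0.58, adjusted p = 0.00096), and Cyp26b1, which breaks down retinoic acid. Alpl stood at 38.9 CPM on day 1 and 265 on day 10 and did not pass the test (adjusted p = 0.071).

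Markers of osteoblasts moved with these genes. Of the 12 measured osteoblast and osteocyte genes 8 rose and 1 fell, also adjusted over the list alone, with a median of 1.71 ± 1.43. Phex rose from 0.321 to 23.3 CPM, and Postn fell by 0.82 on the log2 scale. Library 2 of day 10 held 58.4 CPM of Phex, and library 1, the next highest, held 15.5. Col1a1, the main collagen of bone and fibrous tissue, had a mean of 9529 CPM on day 1 and 26161 on day 10 and did not pass the test (adjusted p = 0.11). Its day 10 libraries held 15620.0, 61220.0, 7793 and 20010.0 CPM, in the order of their numbers. With libraries 3 and 4 of each day alone, the collagen gene Col1a2 was at -1.28 (log2), of the opposite sign to all libraries. Of the 15 fibroblast and tendon genes 6 rose and 2 fell, and of the 5 measured adipocyte genes 3 rose and 1 fell, both also adjusted over the list alone. Few genes of other cell types reached a mean of 1 CPM. They were 4 of 14 macrophage and osteoclast genes, of which Ctsk rose, 4 of 14 neural genes, of which Map2 fell, and 2 of 13 each for endothelium and skeletal muscle. Of the muscle genes both rose, and 1 of them, Tnnc2, shares 592 of its 800 annotated exon bases with Ube2c on the opposite strand.

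Most measured genes of several signalling and matrix-turnover lists rose over the same interval. Such calls were common among all genes, as limma called 2939 of 12109 higher and 3044 lower on day 10 than on day 1. Of 34 lists placed among random lists of like expression, 21 had day 10 medians above the central range and 5 below. Of 14 hedgehog and parathyroid hormone-related protein pathway genes 10 rose and 0 fell, of 20 FGF, IGF and natriuretic peptide genes 14 rose and 1 fell, and of 23 Wnt genes 13 rose and 1 fell. Adjusted over the list alone the counts were 10 and 0, 15 and 1, and 16 and 2. The gene that fell in the FGF group was Fgfr3, a receptor that restrains growth plate chondrocytes (234 to 111 CPM, adjusted p = 0.0012). Ghr, the growth hormone receptor, rose from 14.8 to 95.3 CPM. Sfrp4, a Wnt antagonist, had 3 reads on day 1 and 4802 on day 10, a ratio of 1134 (388 to 5501). Of 26 BMP and TGF-beta genes 7 rose and 6 fell (8 and 7 adjusted over the list alone), with a list median at percentile 91.45 among random lists of like expression. Of 22 matrix protease genes 15 rose and 1 fell, and of 24 collagen processing genes 15 rose and 1 fell (16 and 1 in both, adjusted over the list alone). Htra1 rose from 4.97 to 93.4 CPM and Comp, an extracellular protein of cartilage, from 13.6 to 127 CPM. Of the 18 cartilage matrix genes 8 rose and 1, Col9a3, fell, also adjusted over the list alone. Of the 11 resting and round chondrocyte genes 3 rose and 1 fell, also adjusted over the list alone, with a list median of 0.56 ± 0.49. Col2a1 stood at 5346 CPM and Acan at 357 CPM, which did not differ from day 1 by the test (adjusted p = 0.85 and 0.42). Of 12 chondrogenic regulators 3 rose and 5 fell, also adjusted over the list alone, with Sox9 (log2 -1.34 ± 0.38, adjusted p = 0.0094) and Sox6 (-1.57 ± 0.24) among the fallen. Of 23 genes of proteoglycan synthesis 9 rose and 8 fell (10 and 8 adjusted over the list alone). Of 45 genes of short stature and skeletal dysplasia 16 rose and 9 fell (19 and 10 adjusted over the list alone), with Pth1r, Col11a2 and Comp the highest and Col10a1, Kif22 and Col9a3 the lowest.

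Cell division genes remained low. All 25 S phase, all 25 G2 and M phase and all 25 measured replication-dependent histone genes were lower on day 10 than on day 1, over all genes and adjusted over the list alone. Their medians were -1.13 ± 0.20, -2.002 ± 0.57 and -1.35 ± 0.43. Histone genes are near-identical copies of each other, so values for single members are uncertain. Mki67 fell from 699 to 277 CPM (adjusted p = 0.0081). Myb, Ankrd1, Ptx3 and Tmeff2 had the lowest log2 differences of the named genes, at -3.59, -3.38, -3.38 and -3.30. Altogether 1439 genes were at least 2-fold higher on day 10 and 740 at least 2-fold lower, of which 1391 and 728 passed limma's test. At any size limma called 2939 higher and 3044 lower, and the lower ones became 1927 without the libraries numbered 3.

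**Figure D2:**
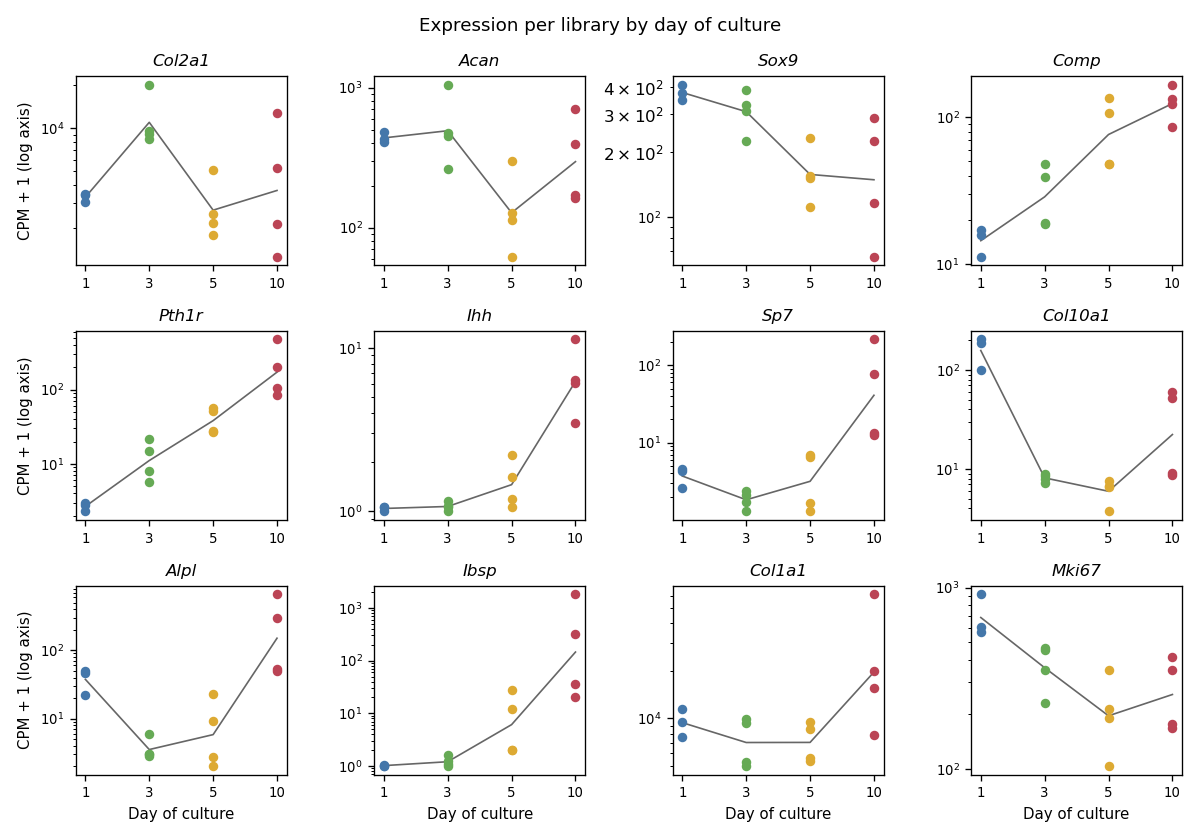
Expression of 12 of the genes chosen before the data were examined, in CPM on a log axis after adding 1, by day of culture (days evenly spaced). Each point is 1 library, and the line joins the day means of log2(CPM + 1). Pth1r and Ibsp were higher on each successive day, Col10a1 was highest on day 1, and the 4 libraries of day 10 were far apart for Ibsp, Alpl and Sp7.

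The fourth comparison covered the step from day 3 to day 5, where fewer genes differed. Gpnmb, the haemoglobin scavenger gene Hp, C4b, Fgl2 and Sfrp4 had the highest log2 differences, at 3.60, 3.55, 3.49, 3.398 and 3.103. Among genes of cartilage, Comp rose (log2 1.41 ± 0.37, adjusted p = 0.029) and several fell. Ucma, a secreted protein of upper growth plate chondrocytes, went from 91.5 to 12.7 CPM (log2 -2.78 ± 0.45, adjusted p = 0.0026), and Scrg1 from 19.2 to 2.65 CPM. Col2a1 fell from 11815 to 2908 CPM (adjusted p = 0.036) and Acan from 559 to 149 CPM (adjusted p = 0.03). Cdsn, Nts and Aldh1l2 fell too, with log2 differences of -2.51, -2.36 and -2.27. In total 297 genes were at least 2-fold higher and 152 at least 2-fold lower, of which 242 and 116 passed limma's test. At any size limma called 618 higher and 488 lower. These calls rested on the libraries numbered 3 and 4, since 8 higher and 1 lower were left without those numbered 3, and 29 and 6 without those numbered 4. The genes at 2-fold were 294 and 124, and 275 and 119, in these fits. Without single libraries the calls were 228 and 115 (library 3 of day 3), 229 and 110 (library 4 of day 3), 364 and 224 (library 2 of day 5), 352 and 184 (library 3 of day 5) and 303 and 179 (library 4 of day 5), and without the libraries numbered 1 the higher ones were 382. All libraries share 1 fit, and without library 4 of day 10 the calls were 911 and 880. The genes 2-fold lower became 275 without the libraries numbered 1 and 239 without library 1 of day 5. With libraries 1 and 2 of each day alone limma called 0 and 0 genes, with 771 genes at an unadjusted p under 0.05.

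The last comparison covered day 5 to day 10. The highest log2 differences belonged to Alpl (8.21 to 265 CPM, log2 4.69 ± 0.82, adjusted p = 0.0042), Ibsp (4.57 ± 1.12, adjusted p = 0.027), Sp7 (3.69 ± 0.78), Prex1 (3.60 ± 0.70) and Kcnma1 (3.51 ± 0.74). Pth1r, Ihh and Mmp13 rose as well, by 2.17 ± 0.49, 2.10 ± 0.30 and 2.75 ± 0.45 on the log2 scale. Runx2 rose from 113 to 267 CPM (adjusted p = 0.017), and Col10a1 from 5.17 to 31.6 CPM (adjusted p = 0.049), below its day 1 level. In the order of their numbers, the libraries held 5.8, 6.6, 2.7 and 5.5 CPM of Col10a1 on day 5. On day 10 they held 8.1, 7.6, 51.2 and 59.6 CPM, so its rise lay mainly in libraries 3 and 4. Rmst, L1cam, Plekha7, Gpr179 and Lcn2 had the lowest differences, at -2.35, -1.96, -1.95, -1.91 and -1.86. The day 10 libraries were far apart in the genes that rose most, with Alpl at 297, 664, 51.7 and 48.2 CPM and Sp7 at 76.3, 214, 11.6 and 12.3 in the order of their numbers. In total 376 genes were at least 2-fold higher and 53 at least 2-fold lower, of which 228 and 33 passed limma's test. At any size limma called 454 higher and 245 lower. Without the libraries numbered 4 it called 77 and 13, without those numbered 3 it called 105 and 12, and without those numbered 1 it called 162 and 59. With the library number as a block it called 871 and 636, and with libraries 3 and 4 alone 915 and 541. Without library 3 of day 5 it called 191 and 68, without library 4 of day 5 it called 199 and 67, and the lower ones were 380 without library 3 of day 10, 160 without library 3 of day 1 and 154 without library 4 of day 1. The genes 2-fold lower became 81 without the libraries numbered 3, 80 without library 2 of day 5 and 91 without library 3 of day 10.

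Across the 4 days, 785 genes had a higher day mean at each step and a difference of 2-fold or more in all, and 344 had a lower one at each step. The single steps were not tested for this count. Of these genes, 776 and 341 passed limma's test between day 10 and day 1. Pth1r, Comp, Gpnmb, Npnt, F13a1, Itgbl1 and Sfrp4 were among those higher at every step, and Myb, Tmeff2 and Hpgd among those lower at every step. The falling count was 173 without library 4 of day 10, 184 without the libraries numbered 4 and 538 without those numbered 2.

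**Figure D3:**
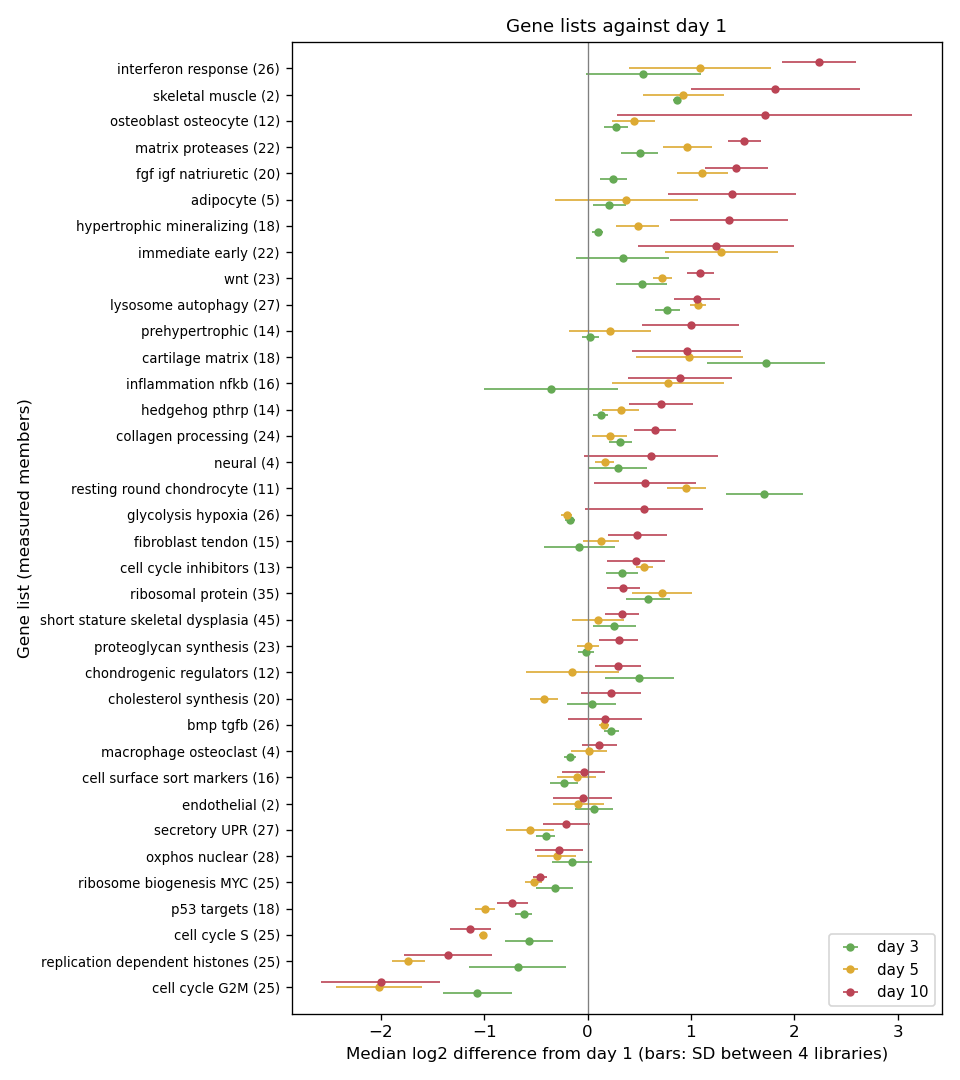
Median log2 difference from day 1 of the measured members of 36 gene lists fixed before the data were examined, on days 3, 5 and 10. Bars show the SD of the medians between the 4 libraries of the day. The S phase, G2 and M phase and histone lists lie below 0 on all 3 days, and the cell cycle inhibitor list lies above 0. The interferon and mineralizing lists lie higher on day 10 than on days 3 and 5.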

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

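For 78 genes named in the text, each list median and the read totals, the library farthest from the other 3 of its day was measured against the range of the 4 libraries, on days 3, 5 and 10. Of 345 such groups, 22 had a gap beyond Dixon's 95% limit for 4 values. Chance flags about 1 in 20, or 17.3 here. Most of the 22 were in library 2. Over all genes of the naming rule, 51 of 675 groups were flagged, against 33.8 by chance. No explanation was tested for these values.

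On day 3, library 1 stood apart for Col2a1, at 20253 CPM against 8380 to 9532 in the others, and for the BMP and TGF-beta list, whose median difference from day 1 was 0.34 against 0.17 to 0.20. Library 2 stood apart in 6 items. Alpl was at 4.88 CPM against 1.85 to 2.08, Ankrd1 at 2.36 against 1.05 to 1.21, Aldh1l2 at 57.8 against 359.5 to 436, and Cd24a at 711 against 468 to 471. The prehypertrophic list median was -0.14 against 0.02 to 0.04 and the inflammation list median 0.67 against -0.69 to -0.49.

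On day 5, library 1 stood apart in 4 items. C4b was at 86.8 CPM against 176 to 193 and Cxcl12 at 374 against 766 to 857. The cartilage matrix list median was 1.75 against 0.64 to 0.81 and that of the chondrogenic regulators 0.57 against -0.40 to -0.28. Library 2 stood apart in 5 items. Matn1 was at 15.8 CPM against 67.4 to 88.0, Ucma at 4.84 against 13.6 to 16.3, Ifi27 at 32.7 against 10.61 to 11.45 and Oasl2 at 13.4 against 1.58 to 2.46, and the interferon list median was 2.23 against 0.80 to 0.93. Cd200 was at 7.56 CPM in library 3 against 10.42 to 10.6.

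On day 10, library 2 stood apart for Gpnmb, at 31.0 CPM against 369 to 513, for Ankrd1, at 2.24 against 1.52 to 1.58, and for the secretory pathway list, at a median of 0.13 against -0.34 to -0.30. Tnnc2 was at 12.9 CPM in library 4 against 8.72 to 8.99.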

How the results depend on the processing

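The blocks, the edgeR test, the fits on parts of the libraries, the libraries left out singly, plain CPM and the log2 of the day mean were chosen after seeing the data. Scaling left every count of genes within 1.5 times its main value and moved the median of all genes by -0.0789 to 0.0569 (log2). edgeR's quasi-likelihood test on the recovered reads called 3867, 6108, 5982, 1111 and 736 genes for day 3, 5 and 10 against day 1, day 5 against day 3 and day 10 against day 5, of which 3688, 5930, 5776, 1047 and 631 were limma calls of the same direction and 0 of the opposite. Its fitted changes, which add less to each value than 1 CPM, put more genes at 2-fold, with 1162 higher on day 3 than on day 1, 493 higher on day 5 than on day 3, and 522 higher and 119 lower on day 10 than on day 5. The fold counts of genes near the floor followed the pseudocount, as the log2 scale makes them do. With 5 CPM they were, higher and lower, 358 and 221 for day 3 and 713 for the genes higher on day 5 and 889 for those higher on day 10, all against day 1, 151 and 72 for day 5 against day 3, and 192 and 21 for day 10 against day 5, and 221 genes had lower means at each step. With 0.25 CPM, 108 genes were lower on day 10 than on day 5. A filter of 5 CPM left 226 genes higher in that comparison, and lowered the similarity of day 1 with days 3, 5 and 10 to 0.934, 0.873 and 0.859 over its 10492 genes. Requiring limma's adjusted p left 228 and 33 there. A log2 threshold of 2 gave 493 and 89 genes for day 10 against day 1, fewer by its construction.

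With libraries left out, the fold counts ranged over 102 to 275 for genes lower on day 5 than on day 3 and 53 to 91 for those lower on day 10 than on day 5, and genes with lower means at each step over 173 to 538. The called genes, higher and then lower, ranged over 830 to 2275 and 705 to 2577 for day 3, 1979 to 3407 and 1846 to 3408 for day 5, and 1927 to 3474 for genes lower on day 10, against day 1. They ranged over 8 to 911 and 1 to 880 for day 5 against day 3, and 77 to 625 and 12 to 380 for day 10 against day 5. The low ends of the called genes came without the libraries numbered 3 or 4, except for genes lower on day 3, where they came without those numbered 1.

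With libraries 1 and 2 of each day alone (1 library on day 1, assumed to vary like the others), limma called 106 and 27, 776 and 599, 742 and 374, 0 and 0, and 14 and 0 genes in the 5 comparisons, with 771 and 1181 genes at an unadjusted p under 0.05 in the last 2. For day 10 against day 5, 144 genes were 2-fold lower, and 172 had lower means at each step. With libraries 3 and 4 alone it called 1184 and 901 for day 5 against day 3 and 915 and 541 for day 10 against day 5, with 273 and 152 genes 2-fold lower, and 727 had lower means at each step. The cause was not tested. Without day 5, 1225 genes had higher and 659 lower means at the remaining steps, and 139 had lower ones without day 1 and 701 without day 10, by fewer steps or a shorter span.

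Pairing was checked from the deviations of the libraries from their day means. Same-numbered libraries correlated at -0.067 to 0.727, with 17 of 21 pairs over 0.1, and 12 of 15 libraries correlated best with one of their own number. The median correlation was 0.258 for same-numbered libraries and -0.094 for other libraries of different days. Deviations cancel out within a day, so positive values for same-numbered libraries make the others negative, and the second median is no separate evidence. Same-numbered libraries thus tended to share deviations, and so did libraries 3 and 4 across numbers on days 3 and 5. Library 4 of day 3 correlated at 0.549 with library 3 and 0.424 with library 4 of day 5. For library 3 of day 3 these were 0.56 and 0.492. The labels do not give the numbers a meaning and 4 pairs did not reach 0.1, so the main fit left the libraries unpaired. The blocked fits are given beside it. With the library number as a replicate block limma called 990 genes higher on day 5 than on day 3, and 871 higher and 636 lower on day 10 than on day 5, and a block of libraries 1 and 2 against 3 and 4 gave 420 lower there. All other blocked counts were within 1.5 times. Among named genes, with libraries 3 and 4 alone for day 10 against day 1, Cdkn1a was at -0.68, Grem1 at 0.65, Col1a2 at -1.28 and Timp1 at -0.51. Each of these passed limma's threshold in that fit (adjusted p = 0.00225, 0.00234, 0.00309 and 0.00414). With libraries 1 and 2 alone Mvd was at -0.11. All of these values were of the opposite sign to those of all libraries, and the cause was not tested. The mean of the BMP and TGF-beta list on day 3 was -0.29 and its median 0.23. Over the alternatives fixed before the data were examined, 2614 values of named genes kept their direction and side of the threshold, 131 lost the call and 20 gained it. Over those added later the numbers were 4980, 235 and 72, with 95 of the lost calls from libraries 1 and 2 alone, and the replicate block lost 2 and gained 11 of 252. Of the list medians 777 moved by less than the spread between libraries and 86 by more. The alternative without mitochondrial genes removed only small RNA genes. Depth limits the genes with 1 to 3 reads on day 1, which include Ihh, Mmp13, Ibsp, Hp, C4b, Sfrp4, Fgl2 and Lcn2. Their ratios to day 1 have only wide counting intervals.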

Other observations

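Several groups of genes outside the cartilage programme moved with time in culture. Of 26 measured interferon-response genes 24 rose from day 1 to day 10 and 0 fell, also adjusted over the list alone, with a list median of 2.24 ± 0.36 (SD between libraries). Ifi27 rose from 1.91 to 46.4 CPM, Ifit3 from 0.669 to 21.2 and Oasl2 from 0.365 to 15.4. Of 22 immediate-early genes, which respond fast to growth factors and stress, 15 rose and 1 fell (17 and 1 adjusted over the list alone). Egr1 rose from 4.85 to 176 CPM (log2 4.79 ± 0.42, adjusted p = 6.8e-07). The gene that fell was Fosl1, which shares 57.2% of its exon bases with Ccdc85b on the opposite strand. Of 16 inflammation genes 8 rose and 3 fell, also adjusted over the list alone. The chemokine gene Cxcl12 rose from 20.5 to 1086 CPM and the prostaglandin enzyme gene Ptgs2 fell from 42.7 to 8.3. Of 27 lysosome and autophagy genes 24 rose and 0 fell (26 and 0 adjusted over the list alone). Ctsf rose from 13.3 to 106 CPM.

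Growth-related genes moved apart. Of 35 ribosomal protein genes 12 rose and 0 fell on day 10, also adjusted over the list alone, while of 25 ribosome biogenesis genes 0 rose and 16 fell, also adjusted over the list alone. Ddx21 fell from 679 to 388 CPM. Of 18 p53 target genes 3 rose and 10 fell, also adjusted over the list alone, with Ccng1 and Plk2 lower (log2 -1.18 ± 0.12 and -1.48 ± 0.15). Of 13 cell cycle inhibitor genes 6 rose and 3 fell (7 and 3 adjusted over the list alone). Of 26 glycolysis and hypoxia genes 12 rose and 1 fell, also adjusted over the list alone, with Car9 higher (log2 2.59 ± 0.55). Of 28 nuclear genes of oxidative phosphorylation 0 rose and 7 fell (0 and 3 adjusted over the list alone), and of 20 cholesterol synthesis genes 4 rose and 0 fell (2 and 0). Of 27 secretory pathway genes 2 rose and 8 fell (2 and 6), among them Creb3l1, which rose from 5.26 to 126 CPM. The oxidative phosphorylation, cholesterol synthesis and secretory pathway medians lay at percentiles 5.79, 97.41 and 15.35, within the central range of random lists. Of 16 cell surface markers used in sorting 4 rose and 2 fell, also adjusted over the list alone. Their list median lay at percentile 39.21 among the random lists. Cd200 rose from 0.813 to 71.2 CPM and Cd24a fell from 1635 to 393. The day 10 libraries held 46.6, 211.4, 17.2 and 9.7 CPM of Cd200 in the order of their numbers.

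Of the tests of explanations below, those on library 2 alone, on a constant difference between library numbers, on a single day 1 library and on the splits of the libraries were chosen after the result was seen. The labels give no difference within a day that could be set against the day 10 spread. The 0.17 below bears only on progress along the course, which it cannot isolate. On day 10, 118 genes were at least 2-fold higher in both of libraries 1 and 2 than in both of libraries 3 and 4, and 55 the other way. The same division gave 36 and 3 genes on day 3 and 66 and 14 on day 5. Of 30 measured mineralizing and osteoblast genes, 9 were among the 118, and 73 of the 118 rose between day 1 and day 10. Library 2 alone is argued against, as library 2 paired with library 3 or 4 had at most 3 such genes, although over the 30 genes the median of library 1 above the mean of libraries 3 and 4 was 0.67 (log2, 95% bootstrap interval over genes -0.13 to 1.45) and -0.10 over the 21 outside the 118. The 118 genes differed by a median of 0.34 on day 3, 0.55 on day 5 and 2.45 on day 10, and a difference constant over the days stays open, since choosing the genes on day 10 raises the last value. A candidate explanation that also stays open is that libraries 1 and 2 were further along the course. The first principal component went both ways. On day 3 libraries 1 and 2 stood at -0.11 and -5.31, further from day 1 than libraries 3 and 4 at -18.5 and -19.8. On day 10 libraries 3 and 4 stood further, at 34.9 and 49.2 against 31.7 and 26.9. Col10a1, which rose between day 5 and day 10, was also higher in libraries 3 and 4 of day 10. The 913 genes whose mean over libraries 3 and 4 was higher by 1 or more on day 10 than on day 3 were higher in libraries 1 and 2 on day 5 by a median of 0.17, above 0.02, the upper bound of the central range of random lists. These genes were chosen partly for low values in libraries 3 and 4 on day 3. The deviations of libraries 3 and 4 on days 3 and 5 correlated at 0.424 to 0.56. Such a choice can raise the day 5 median by itself, so the 0.17 does not decide the question.

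The high day 1 level of Col10a1 was seen in each library. Its lowest day 1 value was 100.2 CPM and its highest later value 59.6 CPM, so 0 of the 3 day 1 libraries lay within the later range. Reads of Nt5dc1, whose intron holds Col10a1, do not explain it, as Nt5dc1 changed by -0.30 ± 0.17 (log2, SE) from day 1 to day 3 while Col10a1 changed by -4.28. The day of culture itself, which the design names, stays open as untested.

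The rise of interferon-response genes was set against blood cells and sequence composition. Of 8 white blood cell markers, 0 reached a mean of 1 CPM on day 10, and the highest was Lyz2 at 0.732 CPM, which argues against immune cells. After the median of genes of like GC content and transcript length was taken off, the list median over 26 of 26 members was 2.23 against 2.24 before. The day of culture stays open, and what in it goes with the rise was not tested.

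With the libraries taken as replicates, no other division of them called as many genes in any comparison. In each comparison, 1 of the 35 splits of the libraries, the real one, gave as many genes past limma's threshold. With 35 splits no smaller share than 1 in 35 can be reached, and same-numbered libraries tended to share deviations. Chance division is therefore argued against but not excluded. The splits say nothing of differences between cultures if the libraries of a day are technical repeats. The real counts were 3847, 6050, 5983, 1106 and 699 for day 3, 5 and 10 against day 1, day 5 against day 3 and day 10 against day 5, and the highest others were 972, 2803, 4323, 4 and 35. Against day 1, the highest other split was the real one with library 2 of the later day moved to the day 1 libraries. It still holds part of the day difference, so 972, 2803 and 4323 are not a chance level.

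Library 2 had less of the nuclear RNA Malat1 than the other libraries of its day, at 3354, 3650 and 5527 CPM on days 3, 5 and 10. The libraries also differed in how many genes had few reads. Library 2 of day 5 had 270 genes with 1 read and library 3 of day 10 had 391, while the others had 704 to 992.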
